A study of Mus musculus with 6 samples.

How the data were processed

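The series holds 6 microarrays of retina with retinal pigment epithelium from diabetic mice, 3 from eyes injected with human CD34+ bone marrow cells and 3 from eyes injected with PBS, collected 1 week later. Per the labels' protocols, total RNA was isolated with a column kit, the best 3 of 4 samples by RNA integrity number, each above 7, were used, and 50 ng was labelled with biotin and hybridised to a whole-transcript mouse array from Affymetrix (MTA 1.0). Sample groups and replicate numbers come from the sample titles. The labels do not say whether the arrays of a group came from separate animals, so p-values of single features measure the spread between these samples, which may be technical. The labels give the diabetic model for the whole series and not for each sample. The strain is C57BL/6 in the sample labels and C57BL/6J in the design text.

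The authors deposited 1 table of log2 expression values per array. The values run from 2.62 to 19.92 and base 2 is inferred from that range. The highest values exceed the raw log2 range of an array scanner, so the signal was rescaled in a way the sources do not state, and every fold is one on that scale. Affymetrix Expression Console and Transcriptome Analysis Console 3.0 are named per the submitters' processing notes, with no role. The summarization, the normalization method and the genome build are not given in the sources used here. The table has 72688 features, of which 65956 are transcript clusters and 6732 are controls that were left out of all tests. Among controls, 1324 exon features had medians between 10.783 and 11.119 and 5222 intron features between 6.399 and 6.759 on the 6 arrays. Scanner-level detection calls were not used here, and the number of arrays limits the precision: the median residual SD of tested features was 0.197 and the median SE of a fold change 0.154 log2 units.

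Gene names come from the platform annotation given with the data, with repeated symbols counted once and older symbols updated through a table of genes of the GRCm38.p6 assembly. No coordinates are given. Of the transcript clusters 31258 have 1 gene symbol, 1492 have several and 33206 are unnamed here; 31256 of the first kind matched that gene table, and 30702 different genes are named. No gene was named from a feature with several symbols. Where a gene has several features, the one with the highest mean over the 6 arrays was used.

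The choices below were fixed before the data were examined unless said otherwise. Features were tested when their mean log2 over the 6 arrays was at or above the median of all transcript clusters (5.38), which left 32978 features and 17274 genes. The 2 groups were compared as CD34 minus PBS with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. A looser description counts features with an unadjusted p under 0.05 and a change of at least 1.5-fold. Standard errors are limma's moderated errors. For genes under the brightness threshold, values come from a fit of all transcript clusters.

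Gene lists for retinal cell types, neighbouring ocular tissues, blood and immune cells, and pathways were written from general knowledge: 39 lists with 582 different genes, of which 527 were measured. Listed genes without a feature of 1 symbol are not analysed here. The 38 lists with at least 4 measured genes were tested with limma's camera (preset correlation 0.01) against all other genes, over 30702 genes without a brightness filter. The shift of a list is its mean log2 fold change minus that of all other genes. The preset takes a list's genes to vary almost independently, so these camera p-values do not measure the spread of a list between samples. The estimated correlation of called lists ran from -0.065 to 0.84. No list passed with an estimated correlation (lowest adjusted p = 0.14), and fry, which tests whether a list's genes move on balance one way, called 1 list, skeletal muscle. Each list's mean was also set against 10000 random lists drawn from the 200 genes nearest in brightness to each member. Of the 12 lists called, 11 lay outside the 2.5 to 97.5 percentile range of such lists, and the synapse list lay at 24.54. Among lists not called, lens crystallins lay at 0 and heat shock at 99.86. Random lists do not keep the correlation between a list's genes, so these percentiles bear on brightness only and do not back the calls.

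Genes are named by a rule: up to 15 genes per direction past the adjusted threshold by size of change. Where fewer than 12 pass, the direction is filled to 12 by the smallest unadjusted p among genes with at least a 1.5-fold change and no overlap between the groups. There were 21 such genes higher and 27 lower. Predicted genes, RIKEN clones and small RNA genes gave way (15 higher and 9 lower). The 4 members with the smallest p of each called list, the 1 with the smallest p of each other list and 12 genes fixed in advance are named too, 9 of the 12 having a feature of 1 symbol.

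Replicate numbers are shared by the groups. The deviations of same-numbered arrays from their group means correlated at 0.55 for number 1, 0.36 for number 2 and 0.19 for number 3, and each CD34 array correlated best with its own number. By the rule set for this check, a correlation over 0.1 in every pair, the numbers were taken to mark possible pairs. The check is weak with 3 arrays per group, since some matching of the arrays always fits best. CD34 array 1 also correlated at 0.4 with PBS array 3, and CD34 array 3 at 0.09 with PBS array 2. The labels do not say that the samples are paired. The fit with the replicate number as a block is given where it moves a count.

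Alternatives were no brightness filter, a stricter one, features with 1 symbol, quantile normalization, median centring, robust and trended moderation, no moderation, array weights, the replicate block, leaving out each array, other list tests, and another summary per gene. Cyclic loess, with and without the block, and leaving out both arrays numbered 2 were added after seeing the data. The analysis was tested on simulated data with 200 changed features among 32978. Recovery depended on the simulated noise. With SDs drawn from the fitted prior, 0% of 1.5-fold, 0% of 2-fold and 76.5% of 4-fold changes were recovered, with up to 11 false calls. With each feature's own shrunken SD it was 0%, 38.5% and 87.5%, again with up to 11 false calls. The second simulation was run first, and both are given. A planted list shift of -0.5 was called in 20 of 20 simulated runs over 30702 genes, with 2 calls among the 37 other lists over all runs. The simulated genes varied independently, while the estimated correlation of called lists reached 0.84. These runs therefore do not measure false calls of lists whose genes vary together. The planted shift was also larger than that of the hypoxia and glycolysis list (-0.31), the lowest of a called list. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.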

Results

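Gene expression was measured in retina collected together with the retinal pigment epithelium from C57BL/6 mice made diabetic with streptozotocin, a toxin that destroys the insulin-producing cells of the pancreas. The eyes were taken 1 week after an injection into the vitreous of either human CD34+ cells from bone marrow, a fraction rich in blood-forming progenitors, or phosphate-buffered saline (PBS). The comparison asks whether the injected cells altered gene expression in the diabetic retina. Each group held 3 arrays, and the number of arrays limits the precision of every value. Total RNA was hybridised to the Mouse Transcriptome Array, which carries probes for coding and noncoding transcripts. The arrays had similar centres, with median log2 values between 5.312 and 5.452. The mean correlation across features was 0.9902 between arrays of a group and 0.9901 between arrays of different groups.

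The largest difference among the named genes was in Dio2, which encodes the enzyme that converts the thyroid hormone T4 to its active form. Its mean log2 value was 10.39 ± 1.0 (SD, n = 3) in the CD34 group and 7.32 ± 0.24 (SD, n = 3) in the PBS group, a log2 fold change of 3.07 ± 0.49 (SE) or 8.39-fold. Among genes that respond to stress, the co-chaperone gene Bag3 was higher by 1.11 ± 0.27 (SE), the transcription factor genes Atf3 by 0.85 ± 0.17 and Fosl2 by 0.74 ± 0.14, and Nupr1 by 0.62 ± 0.18. Plat, encoding tissue plasminogen activator, had a log2 fold change of 0.78 ± 0.20 (SE), and F3, encoding tissue factor, which starts blood clotting, one of 0.74 ± 0.20. The matrix protease gene Adamts1 had 0.94 ± 0.27, the phosphatase gene Dusp16 0.70 ± 0.17 and the myelin protein gene Pmp22 0.69 ± 0.16. T-cell receptor joining segments Traj54 and Traj38 had 0.74 ± 0.14 and 0.63 ± 0.17. In each of these 12 genes the 3 CD34 arrays lay above the 3 PBS arrays, which was part of the rule that selected them.

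Of the 12 genes named as lower after CD34+ cells, Hk2, encoding the glycolytic enzyme hexokinase 2, had a log2 fold change of -0.89 ± 0.17 (SE), from 13.47 ± 0.20 (SD, n = 3) in the PBS group to 12.57 ± 0.25 in the CD34 group. Crb1, a polarity gene needed for the outer limiting membrane of the retina, had -0.62 ± 0.10. Gabrr3, a GABA receptor subunit gene, had -0.60 ± 0.11, and the receptor gene Gpr37 had -0.61 ± 0.13. The histone gene H2bc21 had -0.72 ± 0.14, Wdr31 -0.76 ± 0.16, Grhpr -0.68 ± 0.16, Narf -0.62 ± 0.12 and the hypoxia-responsive gene Ankrd37 -0.61 ± 0.15. The pseudogenes Pisd-ps1, Pisd-ps2 and Pisd-ps3 had -0.62 ± 0.15, -0.62 ± 0.16 and -0.95 ± 0.23, and because they resemble each other in sequence their separate values are uncertain.

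**Figure D1:**
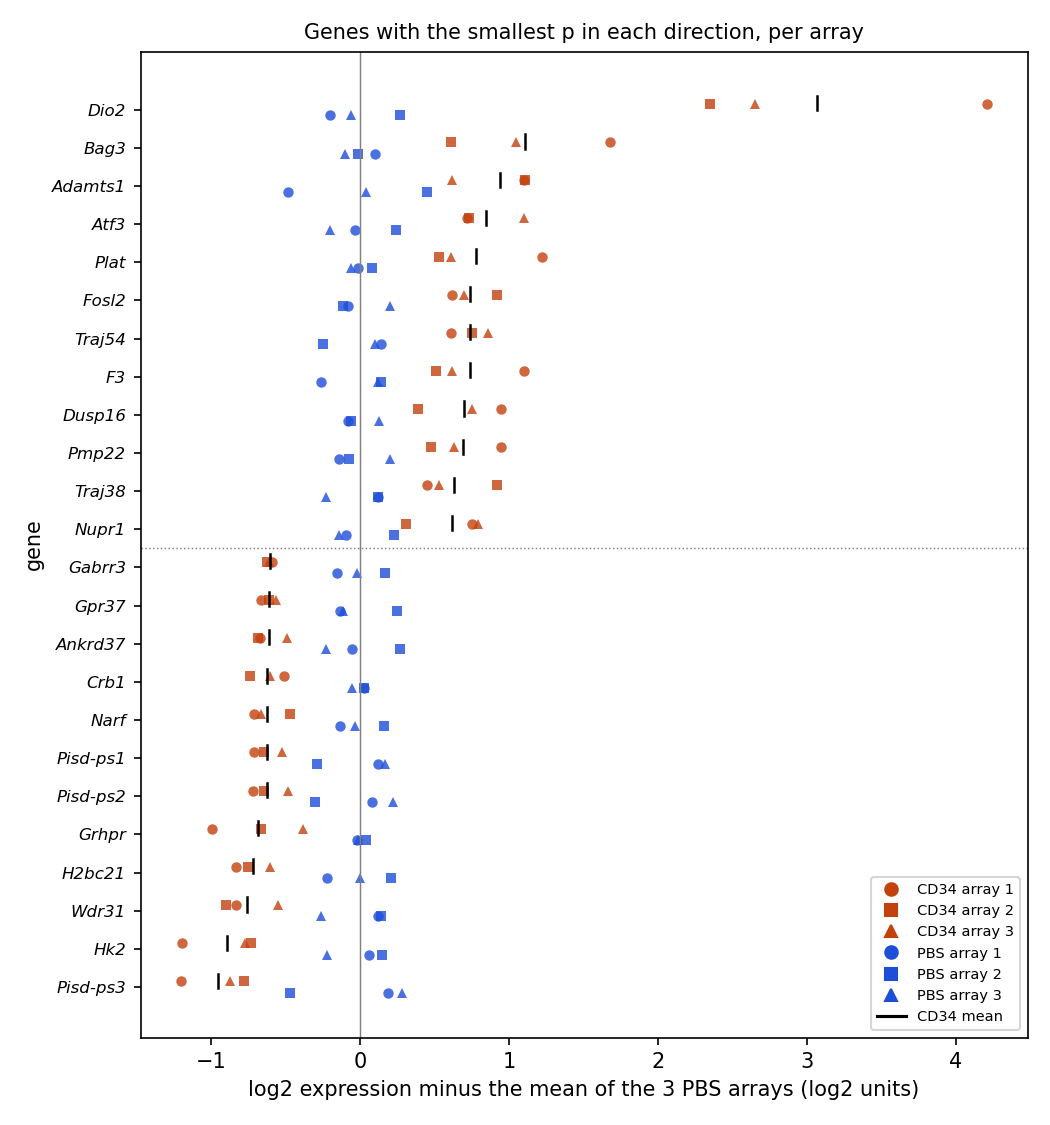
Log2 expression of the 24 genes named above on each array, minus the mean of the 3 PBS arrays (horizontal axis, log2 units); colours mark the groups, symbols the replicate numbers and black ticks the mean of the 3 CD34 arrays. The groups are apart in every gene shown because the rule required it, and Dio2 has the widest spread among CD34 arrays, from 9.67 to 11.53 on the log2 scale.

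None of these single genes passed the adjusted threshold. Of 32978 features tested with limma, 0 had a Benjamini-Hochberg adjusted p under 0.05 and the lowest was 0.92. At an unadjusted p under 0.05 there were 1472 features, where chance alone would give 1649. With the replicate number as a block there were 2331 and the lowest adjusted p was 0.16, the pairing having been judged from these same arrays. The same block gave 1541, 2150 and 401 such features in the other 3 splits that part all pairs of same-numbered arrays. The groups did not overlap in 3723 features, or 11.3%, against the 10% that chance gives for 3 against 3 without pairing. In the other 3 splits that part all pairs of same-numbered arrays the share was 7.2%, 9.2% and 5.1%. The share is not given here for splits that keep same-numbered arrays together. Without the block those splits had 2925, 417, 456, 1762, 998 and 5417 features at an unadjusted p under 0.05, against 1472 in the real split. Past an unadjusted p of 0.05 and a 1.5-fold change, 74 features were higher and 223 lower in the CD34 group, 24.9% higher. Among those with 1 gene symbol 35 were higher and 34 lower, so the excess of lower features lay in those unnamed or with several symbols. The split over all features turned with the scaling of the arrays: 158 higher and 108 lower after quantile normalization (59.4% higher). It was 99 and 193 after cyclic loess (33.9%). With the block the counts were 79 higher and 1014 lower (7.2%), with 0 features past the adjusted threshold. The count of 297 in all became 981 without CD34 array 1 and 541 without CD34 array 2.

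Camera called 12 of the 38 gene lists tested. Splits of the 6 arrays that mix the groups called 0 to 12 lists, so the number of calls does not set the real split apart. Among the 39 gene lists chosen before the data were examined, that of hypoxia and glycolysis genes fell most clearly. Of its 18 measured genes 16 were lower in the CD34 group, with a mean log2 fold change of -0.31, a median of -0.25 and a camera adjusted p of 1.4e-07. The call was not kept with an estimated correlation between the list's genes (adjusted p = 0.51) or with fry, another list test (0.19). Beside Hk2, the phosphofructokinase gene Pfkp had a log2 fold change of -0.46 ± 0.12 (SE), and the collagen prolyl hydroxylase gene P4ha1 had -0.67 ± 0.18. Vegfa, the main vascular growth factor gene induced by low oxygen, had -0.25 ± 0.17 (limma adjusted p = 0.92). Over all genes 0 members passed, and adjusted over the list alone 4 did (Hk2, Pfkp, Ankrd37 and P4ha1). Rod photoreceptors, the most numerous retinal cells, had a mean of -0.05 over 24 genes, and cone genes had -0.21. The rod genes lie at a mean level of 16, where the signal may be compressed, so their mean may understate a change. After cyclic loess the rod list was called by camera (shift -0.117, adjusted p = 4.8e-05).

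The bipolar cell, cone, Mueller glia, synapse and oxidative phosphorylation lists were lower too. Brighter features were lower as a whole: in bins 7 to 10 of 10 equal bins by brightness the median log2 fold change was between -0.036 and -0.094. Random lists matched to these 5 in brightness had means between -0.0526 and -0.0657, and the synapse mean lay within their range, at percentile 24.54. Of 14 bipolar cell genes 13 were lower, with a mean log2 fold change of -0.25 (camera adjusted p = 4.1e-05; adjusted p = 0.51 with an estimated correlation). Its named members were Trpm1, the cation channel gene of ON bipolar cells, at -0.61 ± 0.24 (SE), Car8 at -0.54 ± 0.20, Grik1 at -0.29 ± 0.12 and Lrtm1 at -0.22 ± 0.11. Of 13 cone photoreceptor genes 11 were lower, with a mean of -0.21 (camera adjusted p = 0.00056; adjusted p = 0.60 with an estimated correlation). Cone arrestin, Arr3, had -0.61 ± 0.20, the cone phosphodiesterase subunit gene Pde6h -0.49 ± 0.22, and the cone channel genes Cngb3 and Cnga3 -0.43 ± 0.18 and -0.15 ± 0.09. The 12 measured genes of Mueller glia, the radial glia of the retina, were all lower, with a mean of -0.17 (camera adjusted p = 0.018; adjusted p = 0.51 with an estimated correlation). Sox9 had -0.34 ± 0.16, Hes1 -0.32 ± 0.33, Apoe -0.25 ± 0.23 and the water channel gene Aqp4 -0.22 ± 0.13. Of 14 synapse genes 12 were lower, with a mean of -0.08 (camera adjusted p = 0.043; adjusted p = 0.51 with an estimated correlation). Rims1 had -0.17 ± 0.12, Camk2a -0.15 ± 0.10, Vamp2 -0.13 ± 0.11 and Stx1a 0.13 ± 0.09. Of 18 oxidative phosphorylation genes 17 were lower, with a mean of -0.17 (camera adjusted p = 0.0058; adjusted p = 0.81 with an estimated correlation). Ndufa4 had -0.46 ± 0.35, Cox6c -0.26 ± 0.17, Uqcrfs1 -0.26 ± 0.19 and Sdha -0.20 ± 0.16. In these 5 lists 0 genes passed over all genes and 0 adjusted over the list alone. PBS array 2 was the highest of the 6 in 16 of the 18 oxidative phosphorylation genes, and without it that list's shift was -0.0155 (adjusted p = 0.74).

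The oxidative phosphorylation and Mueller glia calls were lost without CD34 array 1 (shifts against other genes of -0.0771 and -0.13), and the Mueller glia call without PBS array 2 (-0.0992). The synapse call was lost without CD34 array 3 (-0.0378), PBS array 1 (-0.0497) or PBS array 3 (-0.0729). All 3 of these calls were lost after quantile normalization, at shifts of -0.0961, -0.0859 and -0.0315. They were lost too with only genes above the median feature level, at -0.135, -0.129 and -0.0462. After cyclic loess the Mueller glia and synapse calls were lost (-0.121 and -0.0646), and with array weights those of oxidative phosphorylation and Mueller glia (-0.0898 and -0.135). With both arrays numbered 2 left out, the bipolar, cone, Mueller glia and oxidative phosphorylation calls were lost (-0.148, -0.0917, -0.111 and -0.0417). The bipolar and cone calls held without CD34 array 2 at smaller shifts of -0.164 (adjusted p = 0.0066) and -0.133 (adjusted p = 0.038), against -0.251 and -0.214 with all arrays. The oxidative phosphorylation shift was -0.28 without PBS array 1, and the synapse shift -0.133 without either CD34 array 1 or PBS array 2.

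The skeletal muscle, cornea and conjunctiva, retinal pigment epithelium, and lymphocyte and neutrophil lists were higher, at mean levels near or below the median feature level of 5.38. The lens crystallin, lens fibre, ciliary body and sclera lists were not called. All 11 skeletal muscle genes were higher, and in all 11 the 3 CD34 arrays lay above the 3 PBS arrays. Their mean log2 fold change was 0.22 at a mean log2 level of 5.21 (camera adjusted p = 1.4e-07; adjusted p = 0.14 with an estimated correlation), and it was the 1 list that fry called (adjusted p = 0.005). Tnnc2, a fast-muscle troponin gene, had 0.42 ± 0.10 (SE) and was the 1 member past the threshold adjusted over the list alone. Ckm and Tnnt3 had 0.26 ± 0.10 each and Myh1 0.19 ± 0.07. All 10 cornea and conjunctiva keratin and related genes were higher, with a mean of 0.14 at a level of 4.64 (camera adjusted p = 0.0020; adjusted p = 0.66 with an estimated correlation). Krt5 had 0.29 ± 0.10, Krt14 and Krt4 0.18 ± 0.07 each and Krt19 0.18 ± 0.10. Of 17 retinal pigment epithelium genes 16 were higher, with a mean of 0.12 at 5.46 (camera adjusted p = 0.0071; adjusted p = 0.51 with an estimated correlation). Stra6, the receptor for retinol-binding protein, had 0.20 ± 0.09. The pigment genes Mlana, Tyrp1 and Slc45a2 had 0.18 ± 0.07, 0.17 ± 0.09 and 0.16 ± 0.10. Further pigment genes of the list changed less: Oca2 had 0.11, Pmel 0.03, Dct 0.02 and Tyr 0.01. Of 15 lymphocyte and neutrophil genes 14 were higher, with a mean of 0.12 at 4.57 (camera adjusted p = 0.0065; adjusted p = 0.51 with an estimated correlation). Nkg7 had 0.40 ± 0.16, S100a9 0.25 ± 0.12, Cd3e 0.17 ± 0.08 and Cd3d 0.13 ± 0.08. In these last 3 lists 0 genes passed over all genes or adjusted over the list alone. The median over the 23 antigenomic background features lay between 3.518 and 3.644 on the 6 arrays. Their spread was wide: between 47.5% and 60.6% of features on an array lay below their 95th percentile. Levels near or below the median feature level may therefore not stand above background. In the 5 dimmest of 10 equal bins of features by brightness the whole bin was shifted, by medians of 0.038 to 0.066. The calls of the cornea, pigment epithelium and lymphocyte lists were lost after quantile normalization, at shifts of 0.0683, 0.0832 and 0.0532. Cyclic loess ended the pigment epithelium and lymphocyte calls (0.0934 and 0.0732), and with the block the cornea call too (0.0876). With both arrays numbered 2 left out, the cornea and lymphocyte calls were lost (0.0575 and 0.0436). The pigment epithelium call was lost without CD34 array 1 (0.0708), and the cornea and lymphocyte calls without PBS array 2 (0.0824 and 0.0718).

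**Figure D2:**
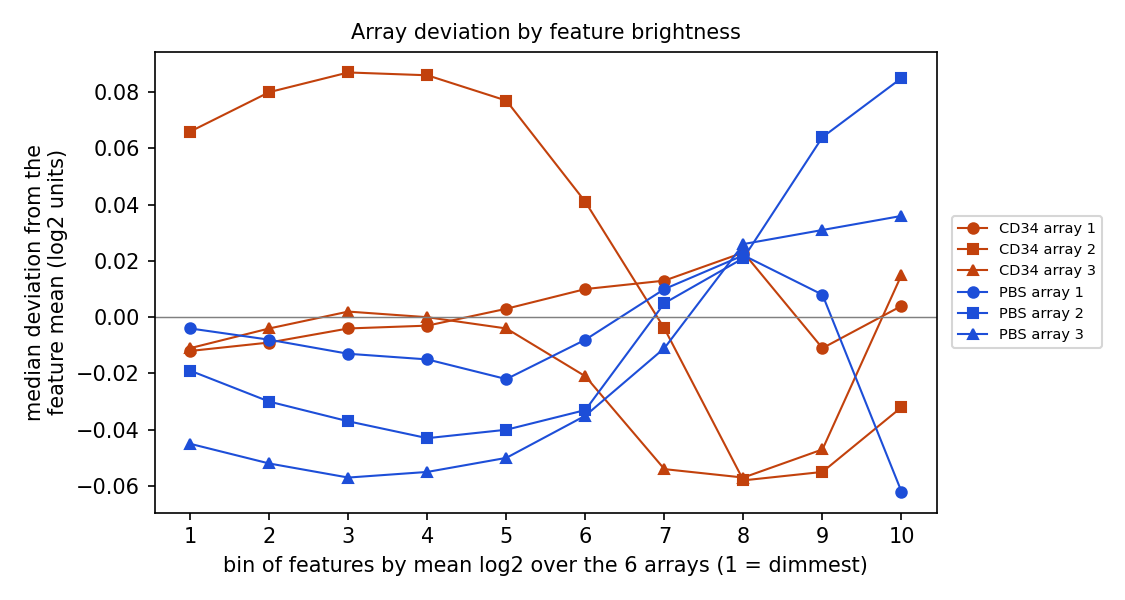
Median deviation of each array from the mean over the 6 arrays (vertical axis, log2 units) in 10 equal bins of the features ordered by that mean (horizontal axis, 1 the dimmest); colours mark the groups and symbols the replicate numbers. CD34 array 2 lies highest among dim features, at 0.066 to 0.087 in the 5 dimmest bins, and PBS array 2 highest in the brightest bin, at 0.085.

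Immediate early genes, which are switched on within minutes of stimulation, were a list that rose. Of 17 measured genes 12 were higher in the CD34 group, with a mean log2 fold change of 0.36 and a median of 0.16 (camera adjusted p = 0.0065; adjusted p = 0.66 with an estimated correlation). Atf3 was the 1 member past the threshold adjusted over the list alone, and 0 passed over all genes. The nuclear receptor gene Nr4a3 had 1.62 ± 0.48 (SE), Fosb 0.50 ± 0.19 and Arc 0.29 ± 0.12. The call was lost without CD34 array 2 (shift 0.0763, adjusted p = 0.15) and without PBS array 1 (0.291, adjusted p = 0.055), and the shift was 0.562 without CD34 array 3. Fos itself was high on the arrays numbered 2 in both groups, at 10.18 on CD34 array 2 and 8.85 on PBS array 2 against 6.24 to 6.83 on the other 4.

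Cholesterol synthesis genes rose as a list. Of 12 measured genes 11 were higher, with a mean log2 fold change of 0.18 (camera adjusted p = 0.0058; adjusted p = 0.66 with an estimated correlation). Insig1, a sterol-sensing regulator, had 0.46 ± 0.18 (SE), the sterol demethylase gene Cyp51 0.33 ± 0.11, and the enzyme genes Sqle and Msmo1 0.24 ± 0.12 and 0.24 ± 0.13. Over all genes and adjusted over the list alone, 0 members passed. The call was lost without CD34 array 1 (shift 0.152) and without PBS array 1 (0.137).

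**Figure D3:**
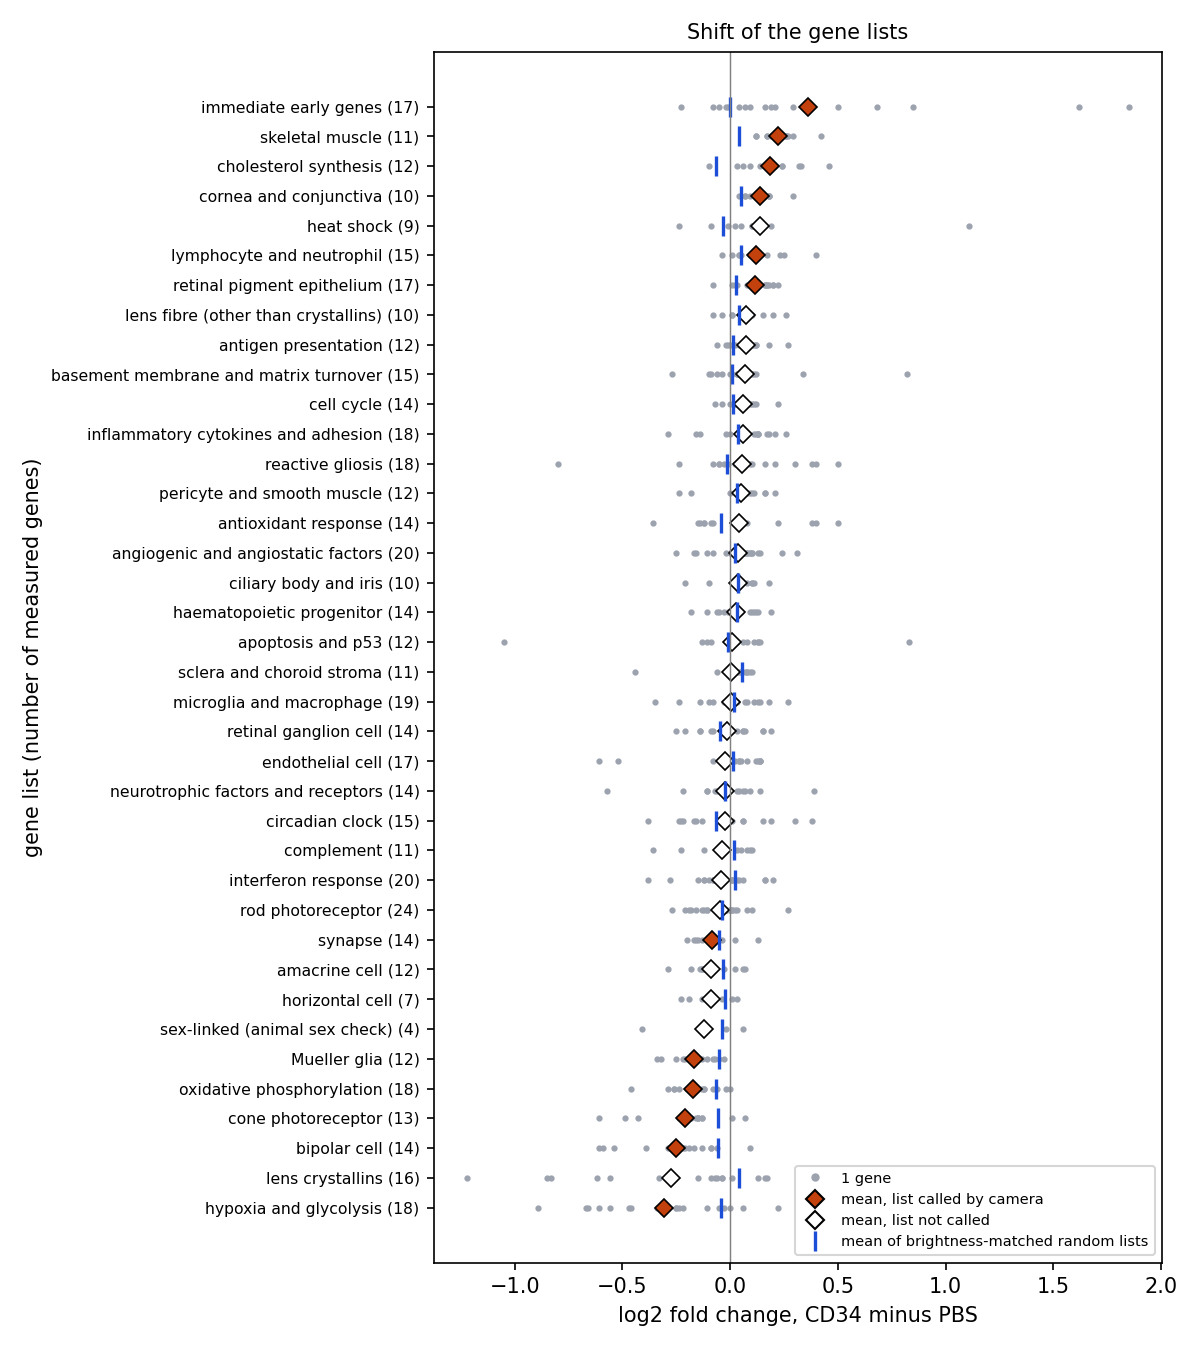
Log2 fold change (horizontal axis, CD34 minus PBS) of each measured gene of the 38 tested lists (grey points), the list mean (diamonds, filled where camera called the list) and the mean expected from brightness-matched random lists (blue bars). The hypoxia and glycolysis mean lies at -0.31 against an expected -0.0421, and that of skeletal muscle at 0.22 against 0.0431.

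The remaining 26 tested lists did not pass, with camera adjusted p between 0.094 and 0.90. Among retinal cells the mean log2 fold change was -0.09 for amacrine cells, -0.09 for horizontal cells, -0.05 for rods and -0.01 for ganglion cells. The rod list was called after cyclic loess (shift -0.117, adjusted p = 4.8e-05, the range over alternatives being 4.8e-05 to 0.92). Without CD34 array 1 the amacrine and horizontal lists were called, at shifts of -0.166 (adjusted p = 0.002) and -0.146 (0.046). The amacrine gene Tfap2b had -0.29 ± 0.14 (SE), Septin4 -0.19 ± 0.12, the rod gene Guca1a 0.27 ± 0.15 and Pou4f3 0.19 ± 0.11. Vascular lists had means of -0.02 for endothelial cells and 0.05 for pericytes and smooth muscle. The transporter gene Slco1a4 of the blood-retina barrier had -0.61 ± 0.20 and Higd1b 0.21 ± 0.09. Angiogenic factors had a mean of 0.04 (Thbs1 0.31 ± 0.14) and neurotrophic factors -0.02, with Lif, a cytokine made by Mueller glia, at 0.39 ± 0.10. Immune lists had means of 0.00 for microglia (Cd14 0.27 ± 0.16), -0.04 for complement (Cfb 0.09 ± 0.08) and -0.04 for interferon response (Oas1a 0.20 ± 0.07). Antigen presentation had 0.07 (Ciita 0.11 ± 0.08) and inflammatory cytokines 0.06 (Cxcl1 0.18 ± 0.09). Haematopoietic progenitor genes had 0.03, with Mpo at 0.19 ± 0.08. Stress and matrix lists had 0.14 for heat shock, 0.06 for reactive gliosis (Cebpb 0.40 ± 0.14), 0.01 for apoptosis, 0.04 for antioxidant genes (Srxn1 0.40 ± 0.21) and 0.07 for basement membrane (Timp3 0.34 ± 0.10). Cell cycle genes had 0.06 (Birc5 0.10 ± 0.07) and clock genes -0.03 (Dbp -0.23 ± 0.09). Ocular tissues had -0.27 for lens crystallins (Crygn 0.17 ± 0.10), 0.07 for other lens fibre genes (Lim2 0.20 ± 0.08), 0.04 for ciliary body and iris, and 0.00 for scleral stroma (Col5a1 0.08 ± 0.07). The lens fibre list was called without PBS array 1 (shift 0.126, adjusted p = 0.049), and the crystallin shift ran from -0.0678 without PBS array 3 (0.83) to -0.552 without PBS array 2 (7.7e-09). Sex-linked genes had -0.12 (Eif2s3y -0.41 ± 0.17), and Slc4a1 of the erythrocyte list, which had too few measured genes to test, had 0.12 ± 0.08. Mean, median and test did not share a sign for clock, endothelial, antioxidant and ganglion cell genes. Adjusted over the list alone, Bag3 passed in the heat shock list. Fas in the apoptosis list had -1.05 ± 0.41, with PBS array 2 at 10.72, and its other feature had 0.26.

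None of the genes chosen in advance for the tissue and the treatment passed the adjusted threshold in limma. The log2 fold change of the glial marker Gfap was -0.01 ± 0.50 (SE), and its sign turned to 0.11 after quantile normalization. It was 0.10 ± 0.13 for Rpe65, 0.14 ± 0.11 for the endothelial gene Pecam1, 0.14 ± 0.09 for the microglial gene Aif1 and 0.03 ± 0.07 for the neurotrophin gene Bdnf, which was -0.01 after quantile normalization. The mouse Cd34 gene had -0.05 ± 0.10 and the leukocyte gene Ptprc 0.05 ± 0.10, which was -0.01 after cyclic loess. The lens gene Cryaa had -0.83 ± 0.49. The array's probes are of mouse sequence, and how many human cells remained was not measured.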

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

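Cyclic loess, with and without the replicate block, and leaving out both arrays numbered 2 were chosen after seeing the data; the other alternatives were planned. The count of 0 features past the adjusted threshold held under every alternative run, with lowest adjusted p between 0.083 (no moderation) and 1.0, and at an adjusted threshold of 0.10. The 297 features past the looser threshold became 1093 with the replicate block (79 higher, 1014 lower), 1079 with cyclic loess and the block, and 848 with both arrays numbered 2 left out. They became 79 with only features of 1 gene symbol and no filter (41 higher, 38 lower), 129 without moderation and 27 at 2-fold. Leaving out each array gave 240 to 981, the highest without CD34 array 1, and 541 without CD34 array 2. The 12 lists called became 7 after quantile normalization, 5 with only genes above the median feature level (3 of the 12, skeletal muscle, cornea and lymphocyte, then had too few genes to test), 10 after cyclic loess (4 of the 12 lost), 9 after cyclic loess with the block (5 lost), 9 with both arrays numbered 2 left out (6 lost), 11 with array weights (2 lost), 1 with fry and 0 with an estimated correlation. With only genes above the median feature level, 4 of the 12 were tested and lost. They were oxidative phosphorylation (shift -0.135, camera adjusted p = 0.13), Mueller glia (-0.129, 0.19), synapse (-0.0462, 0.39) and pigment epithelium (0.167, 0.11). Leaving out each array gave 9 to 15 lists, and the cause was not tested. The replicate block left the 12 list calls in place and changed no other call. The skeletal muscle, hypoxia, bipolar and cone lists were called in all 6 fits that left out an array, with shifts of 0.187 to 0.249, -0.36 to -0.254, -0.343 to -0.164 and -0.264 to -0.133. Signal limits the dim lists: 5.38 was the median feature level, and between 47.5% and 60.6% of features on an array lay below the 95th percentile of its background features. No named gene passed the adjusted threshold in any of 1854 alternative values (lowest adjusted p 0.32).

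None of the 12 called lists turned direction. Among the other lists the direction of the test turned 70 times in 465 alternative values, and the values that follow are shifts against other genes, whose sign is not always that of the test; the cause was not tested. With both arrays numbered 2 left out they were -0.0253 for lens fibre, -0.0364 for ciliary body, 0.0199 for interferon, -0.0542 for basement membrane, -0.0642 for sclera, -0.0439 for haematopoietic progenitor, -0.0986 for endothelial, 0.103 for antioxidant and 0.142 for ganglion cell genes, the last called (adjusted p = 0.029). Quantile normalization gave 0.0524 for clock, -0.0544 for sclera, 0.0149 for neurotrophic, -0.0116 for progenitor, -0.00857 for microglia, -0.0303 for endothelial, 0.0938 for antioxidant and 0.0464 for ganglion cell genes. Cyclic loess, with or without the block, gave -0.0367 for sclera, -0.0108 for progenitor, -0.00838 for microglia, -0.0308 for endothelial, 0.0721 for antioxidant and 0.03 for ganglion cell genes, and with the block 0.0282 for clock genes. Array weights gave 0.0381 for basement membrane, -0.00772 for progenitor, -0.1 for microglia, -0.0618 for endothelial and 0.025 for ganglion cell genes. Only genes above the median feature level gave 0.00968 for progenitor, -0.0417 for endothelial, 0.0921 for antioxidant and 0.00784 for ganglion cell genes. Fry gives no shift, and its direction turned for complement, antioxidant and ganglion cell genes, whose shifts were -0.0412, 0.0405 and -0.0154; the mean of all features of a gene gave -0.0333 for complement, and the replicate block 0.0405 for antioxidant genes.

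Leaving out each array, shifts ran from -0.177 to 0.0815 for clock, -0.0256 to 0.0722 for ciliary body, -0.151 to 0.205 for reactive gliosis, -0.00637 to 0.0596 for angiogenic, -0.13 to 0.0191 for interferon, 0.00666 to 0.104 for basement membrane and -0.0322 to 0.0384 for sclera genes. They ran from -0.0936 to 0.0329 for neurotrophic, -0.148 to 0.2 for antigen presentation, -0.0297 to 0.0532 for progenitor, -0.216 to 0.13 for microglia, -0.229 to 0.0694 for complement, -0.0743 to 0.00931 for endothelial, -0.0187 to 0.0931 for antioxidant and -0.101 to 0.082 for ganglion cell genes. Of the named genes 7 turned sign in an alternative. Log2 fold changes of Gfap were 0.11 after quantile normalization, 0.06 after cyclic loess with or without the block, 0.22 with both arrays numbered 2 left out, and -0.49 to 0.36 leaving out each array. Those of Bdnf were -0.01 after quantile normalization and -0.03 after cyclic loess with or without the block, and Ptprc had -0.01 after the latter. Leaving out each array gave -0.51 to 0.01 for Hes1, 0.0 to 0.18 for Rpe65, -0.1 to 0.01 for Cd34 and -0.02 to 0.12 for Ptprc. The other feature of Fas had 0.26.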

Other observations

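The tests of hypotheses below were chosen after the result was seen, except that of the time of day and the counts over other splits of the arrays; the counts over splits with the replicate block were added after it. Verdicts of the tests on handling and muscle carry-over were also made more cautious after their values were seen, and the test on photoreceptor number was redone on dimmer rod genes after its values were seen.

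Some glial and immune genes had a wide spread within the groups. Serpina3n, an acute-phase gene of reactive glia, ranged from 7.65 on CD34 array 1 to 12.49 on CD34 array 3, and from 9.81 to 11.79 among PBS arrays. CD34 array 3 also had the highest values of Gfap (9.26), the complement gene C1qb (8.87), the protease gene Ctss (9.83) and Stat3 (10.63). Without that array the microglia list had a shift of -0.216 (camera adjusted p = 0.0024), interferon response -0.13 (0.0076), complement -0.229 (0.022) and antigen presentation -0.148 (0.043), while none of these 4 lists passed with all 6 arrays. These genes were picked out after their values were seen.

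Some lens crystallin genes were high on PBS arrays 3 and 1, while Cryab, Cryga and Cryge were highest on CD34 array 2. Crygs was 6.35 and 4.97 there against 3.50 to 4.17 on the other 4 arrays, and Crygb was 6.65 and 6.08 against 3.82 to 4.70. The crystallin list had a mean log2 fold change of -0.27, and camera did not call it with all arrays (shift -0.276, adjusted p = 0.095). The shift was -0.552 without PBS array 2 (7.7e-09), -0.605 with both arrays numbered 2 left out (7.5e-09), -0.516 with array weights (0.00026) and -0.0678 without PBS array 3 (0.83), so it depends on single arrays. The receptor gene Nr4a1 had a log2 fold change of 1.85 ± 0.81 (SE), with 12.61 on CD34 array 2. Xist was between 4.93 and 5.18 on all 6 arrays, and Uty between 10.70 and 10.94. These genes too were picked out after their values were seen.

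The hypoxia and glycolysis list was lower after CD34+ cells. The tables argue against a trend with feature brightness between the arrays: the list's mean lay at percentile 0 of brightness-matched random lists, whose mean was -0.0421, and its shift was -0.289 after cyclic loess, chosen after seeing the data. Rod genes fell less than the list. Rod genes lie at a mean level of 16, where the signal may be compressed, so the 7 no brighter than the brightest hypoxia gene were compared. Their median log2 fold change was -0.056 (95% bootstrap interval -0.16 to -0.025) against -0.25 for the hypoxia list. After cyclic loess it was -0.078 (-0.13 to -0.037) against -0.29. The bootstrap was over the rod genes and does not measure the spread between samples, so the comparison does not decide whether rods were lost. The comparison covers rods only: cone and bipolar cell genes had means of -0.21 and -0.25. After cyclic loess the whole rod list was called by camera (shift -0.117, adjusted p = 4.8e-05), so a loss of rods stays open. Chance variation between the samples was not excluded. The list was not called by camera with an estimated correlation (adjusted p = 0.51) or by fry (0.19), and 0 members passed over all genes. An effect of the injected cells on glucose use is a candidate explanation that was not tested further.

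Dio2 and some single genes that respond to stress were higher after CD34+ cells, with 0 past the adjusted threshold. The heat shock, antioxidant and apoptosis lists were not called (camera adjusted p = 0.44, 0.89 and 0.64). Handling at dissection would raise acute early genes, and 2 of the 3 CD34 arrays lay below the highest PBS array in the mean of 7 such genes. That comparison ignores the possible pairing, though. In all 3 pairs of same-numbered arrays the CD34 array was higher (6.00 against 5.83, 6.94 against 6.51 and 5.95 against 5.92). Handling within pairs may therefore contribute and cannot be told apart from the treatment. Collection at another time of day is consistent with the clock genes: outputs minus opposite-phase genes differed by -0.14, and the groups did not overlap, though by a gap of only -0.93 against -0.92, and 3 against 3 do so by chance in 10% of cases when the pairing is left aside. The whole clock list was not called with all arrays (shift -0.027, adjusted p = 0.34). It was called without CD34 array 2 (-0.177, adjusted p = 0.0014) and with both arrays numbered 2 left out (-0.248, adjusted p = 2.8e-05, the range over alternatives being 2.8e-05 to 0.99), and its direction turned after quantile normalization (0.0524). A response of the retina to the injected cells remains an untested hypothesis.

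The skeletal muscle list was higher at signals near background. The tables argue against brightness alone, since the list's mean lay at percentile 100 of brightness-matched random lists (0.22 against an expected 0.0431). Muscle carried over in dissection in unequal amounts would make the list's genes vary together within groups. The array means of the list were 5.36, 5.30 and 5.32 in the CD34 group and 5.12, 5.09 and 5.09 in the PBS group. The estimated mean correlation within groups was -0.044, with an SD of 0.04 that holds at this estimate and grows with the true correlation. Neither shows amounts that vary within a group, but with 3 arrays per group they do not exclude it, and amounts that differed only between the groups would leave no such trace. Chance was not excluded either: camera with an estimated correlation did not call the list (adjusted p = 0.14), while fry did (0.005). Carry-over, the treatment and chance at signals near background cannot be told apart here.

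With 10 splits of the 6 arrays into 3 and 3, no share under 0.05 can be reached. Features past the adjusted threshold numbered 0 in the real split and at most 0 in the others, so all 10 splits had as many. Features past the looser threshold numbered 297 against a highest other of 2055, and 6 of the 10 splits had as many. Lists called numbered 12 against a highest other of 12, in 2 of the 10 splits. The other splits, which mix the groups, called 4, 7, 8, 5, 8, 0, 7, 8 and 12 lists. Most groupings that do not follow the treatment thus called lists too. The split with 2055 features, CD34 array 1 with PBS arrays 1 and 3 against the rest, had the highest count of the 10. Its count is several times the real one and may reflect a structure of the samples other than the treatment, which was not tested. Among the 4 splits that part all 3 pairs, the counts of features were 297 in the real split and 223, 445 and 55 in the others, and those of lists 12 against 8, 8 and 12. Fitted with the replicate block, these 4 splits had 1093 features in the real split and 467, 937 and 78 in the others, and 12 lists against 9, 6 and 13.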
